A study of Mus musculus with 6 samples.

How the data were processed

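Gene expression was measured by RNA sequencing in 6 samples of 410.4 cells, 3 in control medium and 3 in NET-conditioned medium, which the labels assign by treatment and number. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a stranded mRNA kit. The authors deposited a single table of counts per gene symbol with the columns of a featureCounts output. Per the submitters' processing notes the tools were STAR 2.7.10a and featureCounts of Subread 2.0.3, and the genome build named is mm10. The strand setting, the handling of reads that map to several places and the annotation release are not given in the sources used here. The deposited counts were whole numbers and were used as deposited, with no earlier normalisation.

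Coordinates are those of the deposited table, counted from 1. Of 38929 nuclear gene symbols compared, 11.6% lay on a span that overlaps their position in the mm10 assembly, so the table's coordinates follow another build or annotation, which is not named here. Between 74.8% and 78.4% of the counts from 1 to 20 were even numbers in each library, where about 50% is expected of reads counted singly. The mates of a pair therefore appear to have been counted separately, and total counts stand for reads and not for fragments. The table held 55809 symbols, of which 25563 had a count in any library. Features of 17 symbols lay on 2 or more chromosomes, and exons of 5033 tested genes overlapped exons of another gene. Genes in multi-copy families and genes with an overlapping partner on the other strand are uncertain for that reason.

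Libraries were scaled by TMM, and genes with low counts were removed by filterByExpr with its minimum count of 10, which left 13956 genes. The tested genes held at least 99.95% of the counts of each library. Groups were compared with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest) in R 4.3.3, with a model of the medium alone. P-values were adjusted by the Benjamini-Hochberg method over all tested genes and called at 0.05. Standard errors came from the fold change and its F statistic, and mean ± SD values are over TMM-scaled CPM. The common biological coefficient of variation was 0.0620, with 31119105 to 64431811 counts per library. Limits for a count of 0 were set at 3 fragments, taken as 6 counts because both mates appear to have been counted, and cover counting error only.

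Before the data were examined, 27 gene lists, the tests, the rule for naming genes and the alternatives were fixed. Of 490 symbols on the lists 489 were found in the table. The 23 lists with at least 3 tested members were tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over those lists. Camera called 10 lists, 8 higher and 2 lower. With the correlation estimated from the libraries 3 of them held (TGF-beta/SMAD targets, extracellular matrix, mesenchymal genes). The rotation test fry, which asks whether a list's genes move on balance in a direction and does not compare them with other genes, called 15 lists, and its mixed version called 22. The rule named 12 genes of the TGF-beta pathway, adhesion and mesenchymal state in advance. It further named the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, the 5 smallest p-values in each direction, and up to 4 members of each list. Uncharacterised gene models were passed over, which left out 1 model among the rises and 0 among the falls. In all the rule took 119 genes, some of which are not reported here, and other genes in the text were singled out after their values were seen.

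Replicates were compared before they were averaged. The log CPM values of libraries of a group correlated with r from 0.991 to 0.995 across genes, which are not independent replicates, and their counts differed by 9.59 to 25.1 times the sampling noise (chi-square per degree of freedom), where double counting of mates alone gives about 2. No pair of libraries thus agreed within counting noise, and each was counted once, which does not show that the cultures were separate. The test was tried on simulated data of 13725 genes for NET-conditioned against control medium, with 50 genes changed at each fold. It recovered 44% of them at a log2 fold change of 0.32, 86% at 1.5-fold, 86% at 2-fold and 100% at 4-fold, and 8.14% of its calls were false. Only 200 genes were changed in the simulation, against 5430 genes called in the data. The adjustment therefore set another cutoff on the unadjusted p, and these shares do not carry over to the data. In simulated lists 2 of 2 moved lists and 0 of the others were called by camera. The simulated genes were drawn independently of one another, so this could not show false calls from correlation between the members of a list.

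Alternatives were other scalings (RLE, upper-quartile factors, library size alone), no low-count filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library in turn. After the data were seen, 4 more were added, namely counts divided by 2, libraries thinned to the depth of the shallowest, features of ribosomal RNA and mitochondria left out, and the trend of each library on GC content and gene length removed. GC content was taken from reference transcripts by gene symbol and was known for 97.5% of tested genes. Figures were drawn with matplotlib from the computed tables.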

Results

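The messenger RNA of 410.4 cells, a mouse mammary carcinoma cell line, was sequenced after 2 days in medium with 0.5% serum. The medium was either a control medium, abbreviated Veh in the sample titles, or a medium into which neutrophil extracellular traps (NETs) had been collected. NETs are webs of DNA, histones and granule proteins that activated neutrophils release. Each of the 2 groups held 3 libraries. The deposited gene counts added up to 64431811, 43923391 and 54585562 in control medium replicates 1 to 3, and to 45487210, 31119105 and 52890140 in NET-conditioned medium replicates 1 to 3. The title of the series places the question with the activation of TGF-beta signalling in metastatic breast cancer cells by NETs. The comparison asked which genes the cells expressed at another level in NET-conditioned medium, which is what 'with NETs' stands for below. The design cannot tell an effect of the NETs themselves from that of anything else that differed between the 2 media.

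With NET-conditioned medium the cells expressed far more of the gelatinase gene Mmp9, which rose 14.0-fold from 127 ± 6.39 to 1770.2 ± 66.6 CPM (counts scaled to library size; mean ± SD, n = 3, adjusted p = 2.55e-17). The hyaluronan synthase Has2 rose 11.1-fold to 456 ± 6.19 CPM (adjusted p = 4.44e-17). The cells expressed less of the prolyl hydroxylase Egln3, which was 4.62-fold lower at 32.1 ± 0.929 CPM against 148 ± 3.69 CPM (adjusted p = 3.33e-15), and of the iron-binding protein gene Ltf, which was 7.92-fold lower at 26.5 ± 2.31 CPM against 209 ± 44.1 CPM (adjusted p = 8.44e-05). The response was broad and mostly of small size. Of 13956 genes tested, 2825 rose and 2605 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 38.9% of the genes tested. Of these, 509 rose and 322 fell by at least 2-fold, while 84.7% of the changed genes changed by less. Scaled by library size alone, 2106 genes rose and 3763 fell, so that 35.9% of the changed genes were higher against 52.0% with the normalisation used here. The CPM values of the groups did not overlap at 6837 genes, 49.0% of those tested, where chance gives 10%. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

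**Figure D1:**
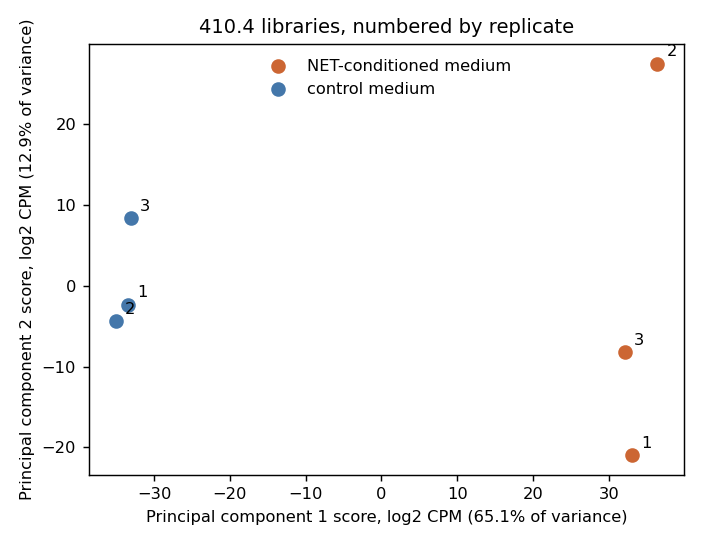
Principal component scores of the 6 libraries, computed from log2 CPM, with the first component (65.1% of the variance) on the horizontal axis and the second (12.9%) on the vertical axis. Points are libraries, coloured by medium and numbered by replicate, and the first component separates the 3 NET-conditioned libraries (scores from 32.1 to 36.4) from the 3 control libraries (scores from -35.0 to -33.0).

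Among the 8 largest rises, Prss46, a serine protease gene, went from 0.851 ± 0.232 to 54.6 ± 3.73 CPM (62.8-fold, adjusted p = 5.95e-16), and the adhesion receptor gene Adgra1 rose 36.6-fold to 22.9 ± 0.692 CPM. Zfp469 rose 27.5-fold, Olfm2 25.4-fold and Postn, which encodes the matrix protein periostin, 18.2-fold. Ccn4, a matricellular protein gene and Wnt target, rose 17.1-fold to 141 ± 10.8 CPM, and Krt14, a keratin of basal epithelial cells, rose 16.2-fold to 102 ± 5.44 CPM. The smallest p-values among the rises also included Pmepa1 and Ctsw, the cathepsin W gene, which rose 12.5-fold to 141 ± 6.27 CPM. Among the falls, the kinase gene Sgk2 was 9.05-fold lower, the glycosyltransferase gene Galnt15 5.73-fold, Fer1l6 5.36-fold, the mitochondrial arginase Arg2 5.25-fold, the integrin gene Itga8 4.76-fold and the transcriptional coactivator Eya2 4.74-fold. The pseudokinase gene Trib2 was 3.23-fold lower and the semaphorin gene Sema3e 2.86-fold lower, at 109 ± 6.25 CPM against 312 ± 13.1 CPM. Each of these genes passed the test with an adjusted p of 1.87e-09 (Postn) or less in edgeR. In the coordinates of the deposited table Mmp9 spans positions 164782700 to 164797770 of chromosome 2, Has2 56529023 to 56557935 of chromosome 15, Egln3 54225767 to 54250646 of chromosome 12, and Prss46 and Ltf 110673574 to 110685590 and 110848339 to 110871835 of chromosome 9. These spans run over exons and introns, and their genome build is open, as the submitters' notes name mm10 while 11.6% of the symbols overlapped their mm10 positions. Exons of Has2, Ctsw, Arg2 and Itga8 overlap genes on the other strand (Has2os, Fibp, Vti1b with Gm48780, and E030013I19Rik), as do exons of other genes named here, and the values of such genes are uncertain because the strand setting of the counting is not given in the sources used here.

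Target genes of TGF-beta and SMAD signalling rose as a group, with the largest median and the smallest p-value of the 23 lists tested. Of 22 measured members 19 rose and 1 fell, both over all genes tested and adjusted over the list alone, with a median log2 fold change of 1.37. The SMAD feedback inhibitors Pmepa1 and Smad7 rose, the first 8.51-fold from 81.2 ± 2.59 to 691 ± 21.2 CPM (adjusted p = 4.44e-17) and the second 3.79-fold from 30.5 ± 2.52 to 116 ± 4.29 CPM (adjusted p = 2.74e-13). Ccn2, the connective tissue growth factor gene, rose 12.1-fold to 383 ± 20.6 CPM, the scaffold gene Nedd9 rose 7.38-fold to 149 ± 4.49 CPM, and the SMAD co-repressor gene Skil rose 3.55-fold to 356 ± 18.1 CPM. The transcription factor genes Snai1 and Junb rose 4.99-fold and 3.58-fold. Klf10, an early TGF-beta response gene, fell by 0.36 on the log2 scale, while Tgm2 (117 ± 5.31 CPM in control medium and 123 ± 4.28 CPM with NETs) and Tgfbi (0.466 and 0.459 CPM) did not pass the test. The list was called higher by camera with the preset correlation of 0.01 between genes (adjusted p = 5.52e-70 over 23 lists) and with an estimated correlation (adjusted p = 0.00529). Of its 26 members, 11 also stand on another list, so the list tests are not independent of one another.

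**Figure D2:**
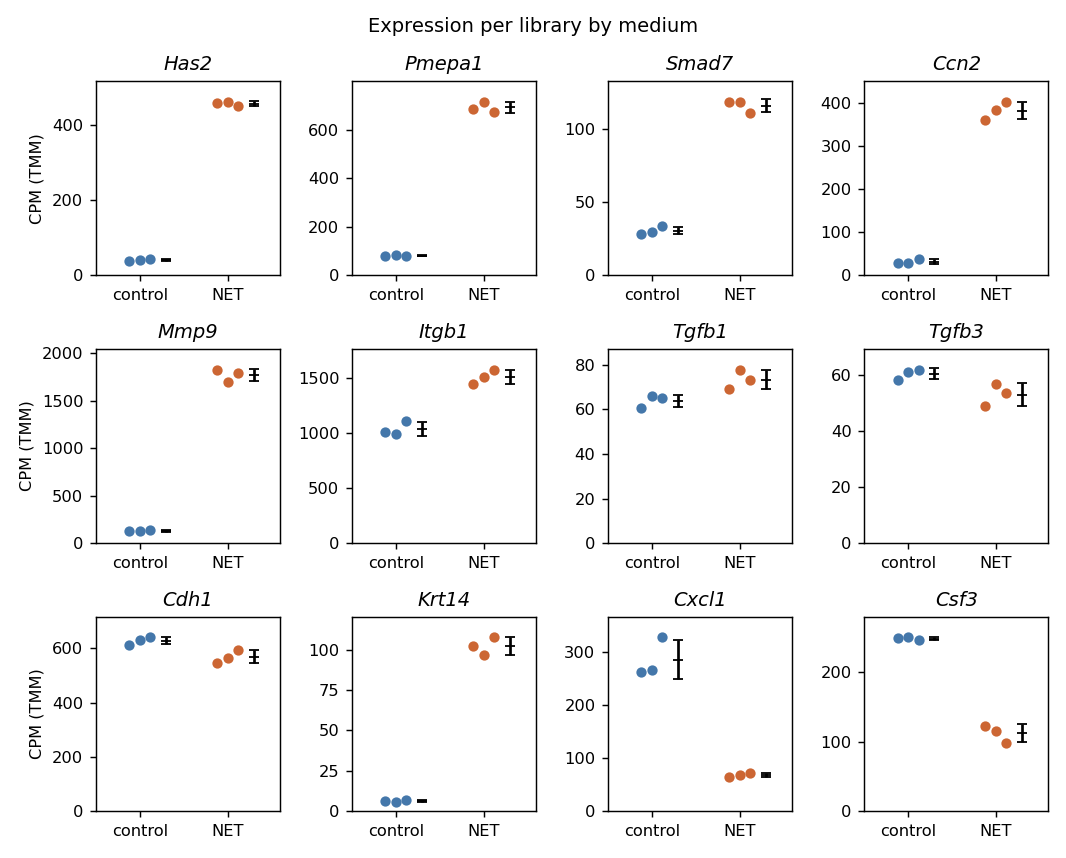
CPM scaled by TMM for 12 genes in each library, with control medium in blue and NET-conditioned medium in orange. Points are the 3 replicates and the black bars show mean ± SD; Has2, Pmepa1, Smad7, Ccn2, Mmp9 and Krt14 lie far above control, Itgb1 and Tgfb1 slightly above, Tgfb3 and Cdh1 slightly below, and Cxcl1 and Csf3 far below.

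The genes of the main ligands, Tgfb1 and Tgfb3, changed by small amounts. Tgfb1 went from 63.9 ± 2.76 to 73.4 ± 4.39 CPM (1.15-fold, adjusted p = 0.0116), Tgfb3 fell 1.14-fold from 60.4 ± 1.99 CPM (log2 fold change -0.19, adjusted p = 0.0197), and Tgfb2 rose 2.60-fold at a low level, from 0.786 ± 0.0488 to 2.06 ± 0.245 CPM. Both signalling receptors fell, Tgfbr1 from 134 ± 2.61 to 107 ± 1.51 CPM and Tgfbr2 from 216 ± 3.86 to 160.2 ± 6.59 CPM, and so did the transducer Smad3, by 0.37 on the log2 scale. Genes whose products bind or release latent TGF-beta moved both ways. Ltbp1 and Ltbp3, genes of latent TGF-beta binding proteins, rose by 0.20 and 0.18 on the log2 scale and Ltbp4 fell by 0.21. The list's members with the smallest p-values were Mmp9, Ltbp2 (2.48-fold), the integrin subunit genes Itgb6 (2.64-fold, to 25.8 ± 1.56 CPM) and Itgb5 (1.97-fold, to 600.03 ± 10.9 CPM), and all rose, as did Mmp14 (1.83-fold). Over the list of TGF-beta ligands, receptors and activators 15 of 22 measured members rose and 5 fell, with the same counts adjusted over the list alone (median log2 fold change 0.38). Camera called the list higher (adjusted p = 3.27e-09), a call that ended with an estimated correlation (adjusted p = 0.167 with an estimated correlation). The call of Tgfb1 was lost without control replicate 1 or NET replicate 2 (log2 fold changes 0.16 and 0.16) and with library size alone (0.13), and that of Tgfb3 without control replicate 2, NET replicate 1 or NET replicate 3 (-0.18, -0.14 and -0.20).

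Of 13 measured integrin genes 7 rose and 4 fell, with the same counts adjusted over the list alone. Itgb1, the common beta subunit, rose 1.46-fold from 1036 ± 63.0 to 1512 ± 64.0 CPM and Itgav rose 1.31-fold to 278 ± 1.48 CPM, while the collagen receptor subunits went apart: Itga2 rose 2.40-fold to 396 ± 9.92 CPM and Itga1 was 3.84-fold lower at 5.80 ± 0.592 CPM. The fibronectin receptor subunit Itga5 rose 2.28-fold to 40.5 ± 2.93 CPM. The list was called higher by camera (median log2 fold change 0.39, adjusted p = 0.00477), with adjusted p = 0.324 with an estimated correlation and 0.0684 in limma-voom. Of the matrix proteases and their inhibitors 12 of 20 rose and 5 fell, also adjusted over the list alone. Timp1, an inhibitor of matrix metalloproteinases, rose 2.03-fold to 74.9 ± 5.67 CPM. The plasminogen activator genes Plau and Plat fell, by 0.42 and 0.69 on the log2 scale, and the lysosomal protease gene Ctsl fell by 0.43. The list had a median log2 fold change of 0.30 and was called higher (adjusted p = 4.56e-12), with adjusted p = 0.135 with an estimated correlation.

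Genes of the extracellular matrix and mesenchymal genes rose, while epithelial genes moved both ways. Of 16 measured matrix genes 10 rose and 2 fell, or 11 and 2 adjusted over the list alone, with a median log2 fold change of 1.04. Tnc, the tenascin C gene, rose 3.62-fold from 36.2 ± 2.01 to 131 ± 2.98 CPM, the collagen gene Col12a1 5.88-fold from 3.94 ± 0.292 CPM, and the laminin gene Lamb3 2.18-fold to 395 ± 3.61 CPM. The list was called higher by camera (adjusted p = 1.88e-14) and with an estimated correlation (adjusted p = 0.0118). Only 9 of 20 mesenchymal genes were expressed highly enough to be tested, and 6 of these rose and 1 fell, also adjusted over the list alone (median log2 fold change 0.68). Snai1, a repressor of epithelial genes, reached 38.7 ± 4.65 CPM and Sparc 9.72 ± 0.552 CPM (4.09-fold). Vim, the vimentin gene, stood at 1.20 ± 0.155 CPM in control medium and 1.48 ± 0.507 CPM with NETs (adjusted p = 0.373), and Twist1 did not pass either (adjusted p = 0.612). The mesenchymal list was called higher (adjusted p = 6.19e-09, and adjusted p = 0.0248 with an estimated correlation). Of its 20 members 8 also stand on another list, among them Snai1, Tnc, Sparc and Itga5, so this call is not separate from those of the other lists.

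Among 22 epithelial genes 8 rose and 5 fell, also adjusted over the list alone. Cdh1, the E-cadherin gene, went from 629 ± 13.2 to 569.7 ± 24.5 CPM (log2 fold change -0.14, adjusted p = 0.0281), and its call was lost without control replicate 2 (-0.14), control replicate 3 (-0.13), NET replicate 1 (-0.12) or NET replicate 2 (-0.14). Besides Krt14 and Lamb3, the plakoglobin gene Jup rose 1.59-fold to 612 ± 10.9 CPM and the tight junction gene Cldn4 2.09-fold to 789 ± 12.3 CPM. Epcam had 685 ± 20.9 CPM in control medium and 655 ± 35.4 CPM with NETs (adjusted p = 0.346). The median log2 fold change of the list was -0.04, but its mean was 0.28 and camera called it higher (adjusted p = 0.00265), with adjusted p = 0.417 with an estimated correlation and 0.196 in limma-voom. Krt14, with a log2 fold change of 4.01, raises that mean, and whether the call holds without Krt14 was not tested. Of 15 target genes of YAP and TEAD, transcription regulators that respond to mechanical cues, 7 rose and 2 fell, also adjusted over the list alone. Nt5e, the ecto-nucleotidase gene, rose 3.73-fold to 403 ± 16.9 CPM, Ajuba 1.76-fold and Amotl2 1.62-fold, while Axl and Ankrd1 fell by 0.48 and 0.36 on the log2 scale. Ccn2, given above, stands on this list as well as on the TGF-beta/SMAD list (log2 fold change 3.59). The median log2 fold change was 0.10, against a mean of 0.53. Camera called the list higher (adjusted p = 1.11e-05), with adjusted p = 0.167 with an estimated correlation. Whether the call holds without Ccn2 was not tested.

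**Figure D3:**
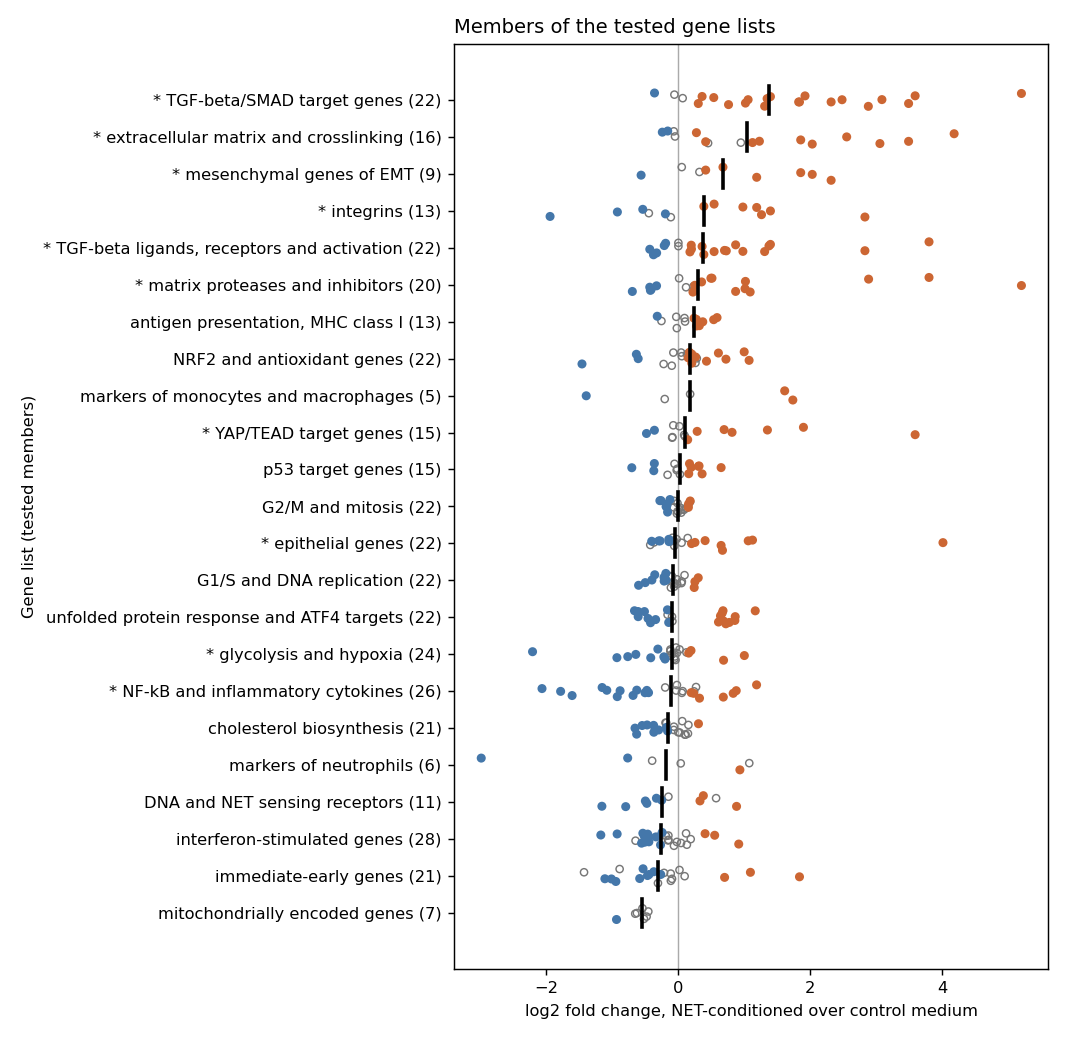
Log2 fold changes, NET-conditioned over control medium, of the measured members of the 23 tested gene lists, ordered by median (black bars). Filled points passed the test (orange higher, blue lower), open points did not, and asterisks mark the 10 lists called by camera with the preset correlation; the median is 1.37 for TGF-beta/SMAD targets and -0.54 for mitochondrially encoded genes.

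Several chemokine genes whose products attract neutrophils and other leukocytes fell. Cxcl1 was 4.18-fold lower with NETs, at 68.3 ± 3.73 CPM against 286 ± 36.3 CPM (adjusted p = 4.74e-10), Cxcl5 3.05-fold lower at 104 ± 6.43 CPM, Ccl20 3.44-fold lower at 12.2 ± 0.368 CPM, and Csf3, the granulocyte colony-stimulating factor gene, 2.22-fold lower at 112 ± 13.1 CPM. Other inflammatory genes went up, among them Csf1, the macrophage colony-stimulating factor gene (1.84-fold, to 225 ± 7.26 CPM), Ptgs2, which encodes an inducible cyclooxygenase (2.28-fold, to 210.3 ± 6.08 CPM), and Tnfaip3, a feedback inhibitor of NF-kB (1.78-fold). Of 26 measured NF-kB and cytokine genes 7 rose and 12 fell, or 8 and 12 adjusted over the list alone. Camera called the list lower (median log2 fold change -0.11, adjusted p = 0.00477), with adjusted p = 0.225 with an estimated correlation and 0.102 in limma-voom.

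Of 28 interferon-stimulated genes 3 rose and 13 fell, also adjusted over the list alone. Rsad2, the viperin gene, was 2.25-fold lower at 32.5 ± 3.46 CPM, the RNA sensor gene Ddx58 1.47-fold and Oasl1 1.38-fold, while Irf1 rose 1.47-fold to 158 ± 2.40 CPM. The list was not called (median log2 fold change -0.26, adjusted p = 0.0526), although it passed without control replicate 3, NET replicate 1 or NET replicate 2 (adjusted p = 0.00149, 0.0421 and 0.0140). Among 11 receptors and transducers for DNA and NETs 3 rose and 6 fell, or 3 and 7 adjusted over the list alone. Tlr4, the endotoxin receptor gene, was 1.74-fold lower at 36.3 ± 0.724 CPM, Aim2 2.23-fold and Cgas 1.41-fold, while Tlr2 rose 1.85-fold to 41.4 ± 3.70 CPM and Ccdc25, the gene of a receptor for NET DNA, 1.26-fold to 48.9 ± 2.11 CPM. This list was not called (median log2 fold change -0.25, adjusted p = 0.186). Of 13 MHC class I presentation genes 7 rose and 1 fell, also adjusted over the list alone, with log2 fold changes of 0.59 for Psmb8, 0.32 for Erap1 and 0.28 for both Tapbp and B2m. The list was not called either (median log2 fold change 0.24, adjusted p = 0.186).

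Proliferation genes shifted by small amounts in both directions. Ccnd1, the cyclin D gene of the G1 phase, was 1.52-fold lower at 1000.4 ± 6.43 CPM (adjusted p = 5.65e-08) and Rfc4 1.28-fold lower, while Mcm7, a replicative helicase subunit, rose 1.23-fold. Of 22 genes of the G1/S transition and DNA replication 3 rose and 8 fell, and of 22 genes of G2/M and mitosis 3 rose and 7 fell, in both cases also adjusted over the list alone. The mitotic genes Cdca8, Aurkb and Kif11 were 1.21-fold, 1.20-fold and 1.14-fold lower, and Ccnb2 rose 1.13-fold. Neither list was called (median log2 fold changes -0.08 and -0.01, adjusted p = 0.186 and 0.539). Among 15 targets of p53, 7 rose and 3 fell, or 7 and 4 adjusted over the list alone. The pro-apoptotic gene Bbc3 was 1.63-fold lower and Trp53inp1 1.28-fold lower, while Phlda3 rose 1.57-fold and Aen 1.29-fold. The p53 list had a median log2 fold change of 0.03 and adjusted p = 0.881, and its direction turned with library size alone and with thinned libraries.

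Stress response genes moved both ways. Hspa5, the gene of the chaperone BiP, rose 2.25-fold from 1441 ± 159 to 3240.3 ± 124 CPM (adjusted p = 1.27e-09) and the transcription factor gene Xbp1 1.71-fold, whereas Trib3 was 1.58-fold lower and Psat1, an enzyme of serine synthesis, 1.52-fold lower at 462 ± 9.24 CPM. Of 22 genes on the list of the unfolded protein response and ATF4 targets 10 rose and 9 fell, or 10 and 10 adjusted over the list alone. The list was not called (adjusted p = 0.231), with a median log2 fold change of -0.09, a mean of 0.16 and an upward direction in camera. Of 22 NRF2 and antioxidant genes 11 rose and 3 fell, or 13 and 4 adjusted over the list alone (median log2 fold change 0.19, adjusted p = 0.231, not called). Gclc, a subunit of glutathione synthesis, rose 1.65-fold, while Slc7a11 and Gstm1 were 1.52-fold and 2.75-fold lower; Ftl1 rose 2.00-fold, a value that is uncertain because ferritin genes have near-identical copies in the genome.

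Of 24 genes of glycolysis and hypoxia 4 rose and 8 fell, or 4 and 9 adjusted over the list alone. Besides Egln3, Aldoc was 1.90-fold lower and Pfkfb3 1.56-fold lower, while Vegfa rose 1.61-fold to 125 ± 7.68 CPM. Camera called the list lower (median log2 fold change -0.10, mean -0.18, adjusted p = 0.0169), with adjusted p = 0.450 with an estimated correlation. Whether the call holds without Egln3 was not tested. Of 21 cholesterol synthesis genes 1 rose and 9 fell, or 4 and 9 adjusted over the list alone, with Lss 1.57-fold, Stard4 1.46-fold and Dhcr7 1.39-fold lower. The cholesterol list was not called (median log2 fold change -0.16, adjusted p = 0.0526), but it passed without control replicate 1, control replicate 2 or NET replicate 1 (adjusted p = 0.0325, 0.00991 and 0.0421). Among 21 immediate-early genes 3 rose and 9 fell, or 3 and 11 adjusted over the list alone, and the list was not called (median log2 fold change -0.31, adjusted p = 0.184). Dusp6, a phosphatase that limits ERK, was 2.16-fold lower at 122 ± 8.21 CPM, whereas Junb, Fosl2 (1.63-fold) and Fosb (2.14-fold) rose; exons of Junb overlap those of Prdx2 on the other strand.

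Most neutrophil markers were near the detection limit. Of 22 neutrophil markers 16 had under 13 counts in every library, and 10 of these, among them Elane, Camp and Ngp, had 0 counts in all 6 libraries, which allows up to 0.193 CPM in the shallowest library (3 fragments, taken as 6 counts, counting error only). S100a8, an abundant neutrophil transcript, rose 1.91-fold to 2.63 ± 0.148 CPM. Ltf fell, and Itgb2 was 1.70-fold lower at 88.7 ± 0.584 CPM. Of the 6 neutrophil markers tested, 5 had at least 1 CPM in control medium, 1 rose and 2 fell, or 2 and 2 adjusted over the list alone. The neutrophil list was not called (median log2 fold change -0.18, adjusted p = 0.0612), but it passed as lower without control replicate 1, 2 or 3 (adjusted p = 0.0235, 4.22e-04 and 0.0214). Of 5 monocyte and macrophage markers tested, 4 of them at 1 CPM or more in control medium, 2 rose and 1 fell, or 3 and 1 adjusted over the list alone. Csf1r, the receptor for the product of Csf1, rose 3.34-fold from 24.1 ± 1.43 to 80.2 ± 5.30 CPM, and Aif1 stayed under 1 CPM. That list was not called (median log2 fold change 0.18, adjusted p = 0.0565) and passed without control replicate 2, NET replicate 1 or NET replicate 3 (adjusted p = 0.0496, 0.0461 and 0.0306). The lists of lymphocytes, red blood cells, fibroblasts and endothelial cells had too few measured members for a list test. Of their measured members Trac rose to 1.29 ± 0.170 CPM, Pi16 fell from 1.39 ± 0.232 CPM to about the limit of a count of 0, which leaves its fold uncertain, and Egfl7 was 1.69-fold lower at 4.02 ± 0.439 CPM, while Klf1 (0.464 ± 0.172 CPM with NETs) and Pdgfra (49.2 ± 2.13 CPM) did not pass. Epor and Cdh5 rose, to 2.08 ± 0.389 and 15.8 ± 1.49 CPM. The call of Epor was lost without control replicate 1 or 2 or NET replicate 1 or 2 (log2 fold changes 0.53, 0.61, 0.57 and 0.57), that of Cdh5 without control replicate 1 or 2 or NET replicate 2 or 3 (0.25, 0.23, 0.25 and 0.21), and both with library size alone (0.59 and 0.20). Adjusted over the list alone these lists had the same counts.

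The share of counts on mitochondrially encoded genes was 0.190 ± 0.0734% with NETs and 0.294 ± 0.0193% in control medium (SD, n = 3, exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). It was 0.112%, 0.258% and 0.200% in NET replicates 1 to 3. The share was taken over all features with a mitochondrial symbol. Of the 13 protein-coding mitochondrial genes it holds 7, as the other 6 (mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l) had at most 4 counts in any library. It is therefore not the full mitochondrial share. Of the 7 mitochondrial genes tested 0 rose and 1 fell, also adjusted over the list alone (median log2 fold change -0.54). That gene was mt-Nd6, at 4.06 ± 1.68 CPM against 7.51 ± 0.384 CPM (adjusted p = 0.00452), while mt-Co1 stood at 479 ± 200.1 CPM against 751 ± 63.3 CPM (adjusted p = 0.237). The list was not called (adjusted p = 0.231) and passed without NET replicate 2 (adjusted p = 0.0351), where mt-Co1 passed too (log2 fold change -1.01). The share of the ribosomal RNA feature Rn18s-rs5 ranged from 0.162% to 0.693% in control libraries and from 0.375% to 1.08% with NETs (exact two-sided permutation p = 0.8).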

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

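The tests with halved counts, thinned libraries, ribosomal and mitochondrial features left out, and a GC and length correction were chosen only after the data were seen. Of the 119 named genes, 109 kept their direction and side of the threshold in every alternative run that tested them. Some named genes were absent from a run, such as the mitochondrial genes where their features were left out. Rises ran from 2106 (library size alone) to 2969 (replicate block) and falls from 2038 (without control replicate 1) to 3763 (library size alone). Falls of at least 2-fold numbered 208 with a filter of at least 1 CPM in at least 3 libraries, against 322, with fewer genes tested (11747 against 13956). With an estimated correlation 3 lists were called, against 10, and the adjusted p was 0.167 for TGF-beta ligands and activation and for YAP/TEAD targets, 0.417 for epithelial genes, 0.135 for proteases, 0.225 for NF-kB, 0.324 for integrins and 0.450 for glycolysis. Limma-voom ended the calls of epithelial genes (0.196), NF-kB (0.102) and integrins (0.0684), and called interferon-stimulated genes (0.0177), MHC class I (0.0493), cholesterol synthesis (0.0431), immediate-early genes (0.0382) and mitochondrial genes (0.0153). Cholesterol synthesis was also called with upper-quartile factors (0.0447), library size alone (0.0268), no filter (0.01001), without ribosomal and mitochondrial features (0.0497) and with the GC and length trend removed (0.0449). Interferon-stimulated genes were called with no filter (0.00375), thinned libraries (0.0483) and without ribosomal and mitochondrial features (0.0497). Neutrophil markers were called with the filter on CPM (0.0358), halved counts (0.0305) and thinned libraries (0.0292), and monocyte markers with library size alone (0.0461). The p53 targets, called in no alternative, turned direction with library size alone (0.993) and thinned libraries (0.987). Apart from the count under that filter, the cause of these changes was not tested.

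Leaving out a library in turn gave adjusted p from 0.00149 to 0.123 for interferon-stimulated genes, 0.00991 to 0.160 for cholesterol synthesis, 0.0351 to 0.304 for mitochondrial genes, 4.22e-04 to 0.0965 for neutrophil markers and 0.0306 to 0.0796 for monocyte markers, and it ended no list's call. Klf1, which passed no test, ranged from -0.27 (without NET replicate 3) to 0.26 (without NET replicate 2) on the log2 scale. The same replicate numbers did not pair the libraries: their deviations from the group means correlated at 0.118, -0.059 and 0.056 across genes, and not every library correlated best with its own number. With the replicate block 2969 genes rose and 2713 fell, and the lists of interferon-stimulated genes (0.0144), cholesterol synthesis and monocyte markers (0.0419 each) and neutrophil markers (1.76e-04) were called. No list lost its call under the block, the call of Epor was lost, that of Cd14 was gained, and no other named gene's call changed. Depth limits genes near the filter, and small changes may have been missed. The simulated recovery of 44% at a log2 fold change of 0.32 came from data with far fewer changed genes. It therefore does not measure the share missed here.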

Other observations

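The gene lists in these first paragraphs were written after the largest changes had been seen, and some of their members were chosen for that reason, so their tests describe these libraries and are not independent. On a list of basal keratinocyte genes 7 of 11 measured members rose and 0 fell, while Trp63 (log2 fold change 0.27, adjusted p = 0.466), Col17a1 (-0.03), Itgb4 (-0.11) and Perp (-0.02) did not pass, and neither did Krt5, the partner keratin of Krt14, which that list left out (-0.37, adjusted p = 0.353). Sfn, which encodes stratifin, rose from 32.8 ± 1.97 to 362 ± 23.2 CPM (log2 fold change 3.46), and the annexin gene Anxa8 by 2.02 on the log2 scale to 218 CPM, beside Krt14. Camera gave the list an adjusted p of 4.75e-21, and 0.00922 with an estimated correlation. Contractile and focal adhesion genes rose too, 9 of 12 with 0 falls, led by the actin-binding gene Palld (log2 fold change 2.12) and the tropomyosin gene Tpm1 (0.88). The adjusted p was 2.55e-07, and 0.0395 with an estimated correlation. Feedback genes of ERK signalling fell, 8 of 12 with 2 rises, among them Dusp6 (-1.11), Spry1 (-1.02) and Fosl1 (-0.94), with adjusted p 5.19e-05, and 0.0395 with an estimated correlation. Of 7 EGF-family ligands 0 rose and 3 fell, Tgfa by 0.51 on the log2 scale, and that list was not called (adjusted p = 0.113).

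The Notch ligand gene Jag1 rose 8.88-fold from 36.1 ± 2.44 to 320.3 ± 18.7 CPM. Of 12 Notch genes 5 rose and 4 fell, with Lfng and Hes1 higher (log2 fold changes 0.90 and 0.46) and Notch1 and Notch3 lower (-0.48 and -0.82). The Notch list had adjusted p 0.0140, and 0.0795 with an estimated correlation. Of 5 measured Wnt targets 2 rose and 1 fell, with Ccn4 far ahead of the others (4.10) and a median of 0.03 (adjusted p = 1.34e-04, and 0.0395 with an estimated correlation). Of 5 kallikrein genes 3 fell, Klk6 by 2.05 and Klk10 by 1.33 on the log2 scale (adjusted p = 1.34e-04, and 0.0496 with an estimated correlation). The 410.4 cells also held transcripts better known from neutrophils. Padi4, whose enzyme citrullinates histones during NET formation, had 195 ± 8.48 CPM in control medium and 200.5 ± 1.26 CPM with NETs (adjusted p = 0.560), while S100a9 had at most 12 counts in any library.

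Of the tests below, those on neutrophil RNA, on ligand messenger RNA, on NF-kB feedback genes and on the spread of the GC and length correction over genes were chosen only after the values they use had been seen. The rise of TGF-beta and SMAD targets was set against carried-over neutrophil RNA, a trend on GC content and length, and more ligand messenger RNA. S100a8 and S100a9 together reached 2.6996 ± 0.123 CPM with NETs (1.49 ± 0.213 in control medium), 0.0732% of the summed rise of 3686 CPM of the list's risen genes, which argues against neutrophil RNA as its source. With the trend removed the list's median log2 fold change was 1.37, as before (1.37). The log2 fold changes of all tested genes moved by a median of -0.01 with an SD of 0.04 over genes and by at most 0.21. These values argue against the trend as the whole cause of the list's rise. The calls of single genes depended on it more, as 818 genes had another call with the trend removed, where 2633 rose and 3063 fell. The summed CPM of Tgfb1, Tgfb2 and Tgfb3 was 1.03 times the control sum (125 ± 4.67 to 128 ± 8.60) and at most 1.14 times in any pair of libraries. Ligand brought in with the NET-conditioned medium or released from its latent form by the cells may account for the rise. This stays open, as the design holds neither a blocked receptor nor a measure of active ligand.

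The fall of Cxcl1, Cxcl2, Cxcl3, Cxcl5, Ccl20 and Csf3 was set against GC content and length and against a general loss of NF-kB transcription. The products of these genes draw or raise neutrophils and other leukocytes, and the genes were taken because they fell. On a list of 8 measured genes of this kind, without Ccl20, 6 fell, with a median of -1.02. That list repeats Cxcl1, Cxcl2, Cxcl3, Cxcl5 and Csf3, so its falls and median are not separate evidence. Of the genes it adds, Csf2 fell (log2 fold change -0.68), Cxcl16 rose (0.34) and Ppbp did not pass. The median of the first 6 genes was -1.35 with the trend removed and -1.38 before, which argues against that trend. Of 5 NF-kB feedback genes 3 were higher (Tnfaip3, Nfkb2 and Relb), Birc3 did not pass (log2 fold change 0.24) and Nfkbia fell by 0.50 on the log2 scale, which argues against a loss shared by all NF-kB targets. A loss at part of them stays open, as 12 of 26 NF-kB and cytokine genes fell and 7 rose and camera called that list lower (adjusted p = 0.00477), and no other biological explanation was tested.

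The chaperone and ATF4 parts of the stress list moved apart. All 10 chaperone and XBP1-related genes rose (median log2 fold change 0.71), and 9 of the other 12 genes fell with 0 rises (median -0.38). The genes had been fixed as a single list, and its division into these parts was not fixed in advance. The difference between the parts therefore describes these genes and is not an independent test. With the GC and length trend removed the difference of medians was 1.11, against 1.09 before. In genes outside the first lists 15 of 17 chaperone and degradation genes rose and 0 fell, while 9 of 18 ATF4 targets fell and 4 rose, among them Ddit4 (1.47), and the medians differed by 0.50 (camera adjusted over both lists p = 1.79e-06 and 0.0268, and 0.154 and 0.229 with an estimated correlation, where neither list is called). These values are consistent with a split between both arms that extends beyond the first genes, as a hypothesis, while another supply of amino acids in the NET-conditioned medium stays open and untested.

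With 3 libraries against 3 there are 10 splits, so the share of splits with a result as large as the real one cannot lie under 0.1. The real split gave 2825 rises and 2605 falls, of which 509 and 322 by at least 2-fold. The highest of the other splits gave 0 of each in edgeR, with at most 776 genes at an unadjusted p under 0.05 (6525 in the real split) and at most 16 genes called by DESeq2. Each of the other splits mixed both media in each group, so the effect of the medium added to the spread within groups. Few gene calls were therefore likely beforehand, and these counts do not measure chance. For the lists called by camera with the preset correlation, the real split gave 10 and the other splits from 1 to 8, although edgeR called 0 genes in those. The groups of those splits held the media in unequal numbers, so part of the medium's effect stayed between them. The list counts therefore do not measure chance either.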
